A study of Spirodela polyrhiza and Pistia stratiotes and Colocasia esculenta with 79 samples.

How the data were processed

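Poly-A RNA was sequenced from dissected regions of Lemna minor clone 8263 (14 libraries), Spirodela polyrhiza clone 9509 (28), Pistia stratiotes (20) and Colocasia esculenta (17). Per the labels, duckweed pieces were recovered from RNAlater and extracted with a micro-scale column kit. Taro Apical and Basal RNA came from a single aliquot of ground tissue. Taro Sheath and Petiole RNA was pooled from 3 aliquots and cleaned with a further kit, so extraction and region are confounded between those groups. Libraries were made by Novogene with fragments of 370 to 420 bp, per the labels. Paired reads of 150 bp and growth at 22 °C are stated in the protocol text of the Spirodela Node and Tract libraries and of Pistia, while for the other libraries they are not given in the sources used here.

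The values were deposited by the authors as TPM, made with Salmon 1.10.0 per the submitters' processing notes. The transcript set, the index and the rule for removing low transcripts are not given in the sources used here. Each transcript of the deposited tables exceeded 2 TPM in at least 1 library, and the columns summed to between 998999 and 999911. The tables held 14856 transcripts for Lemna, 16332 for Spirodela, 19647 for Pistia and 19418 for taro. TPM gives no read depth, so the precision of a single value is unknown. The identifiers are not paired with gene names in the tables, and no annotation was used. The 13 gene lists fixed beforehand, with the test planned for them, were therefore not tested.

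Groups were the regions named in the labels. The Spirodela Node columns carry the numbers 1, 3, 5 and 6, which do not match the labels, and were used as 4 replicates without a number. Whether libraries with the same number came from the same plants or cultures is not given in the labels beyond the words biological replicate. Regions were compared within a species with limma 3.58.1 in R 4.3.3, by a linear model on log2(TPM + 1) with moderated variances and a mean-variance trend. All regions of a species were in the model, without a replicate block. Transcripts were tested if they had at least 1 TPM in at least 2 Lemna, 4 Spirodela, 4 Pistia or 3 taro libraries. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05. A difference on this scale understates the fold of transcripts at low TPM, and where a group was listed at 0 no fold is given. The comparisons, tests, alternatives and the rule for naming transcripts were fixed before the data were examined.

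Transcripts were named by a fixed rule. For each comparison these were the first 2 called in each direction by absolute log2 difference, among those with a mean of at least 10 TPM in the higher region and no overlap between the replicates of both regions. Region-specific transcripts were those called higher in a region than in each other region of the species, and Spirodela Node and Tract were left out of that count because they carry a separate block of labels. Numbers of transcripts at 1 TPM or more, and the share of TPM in the 10 most abundant, were compared by two-sided exact permutation tests with adjustment over the 19 comparisons. Libraries of a species were compared by Pearson correlation. No test was made between species.

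To see whether replicate numbers pair the libraries, the deviations from the region means were correlated between libraries of the same number. Numbers were taken to pair where at least 3 were shared and each such correlation exceeded 0.1. This held for Lemna Basal and NodeTract against Apical, Spirodela Basal against Apical, Spirodela NodeTract and LowerWall against Basal, Pistia Stem against Apical and taro Basal against Apical.

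The alternatives were a pseudocount of 0.1, no filter, median-of-ratios rescaling of the libraries, the replicate number as a block, a fit of the 2 compared regions alone, separate fits of the Spirodela label blocks, Spearman correlation, and leaving out each library in turn. The block in a fit of the compared regions alone, for every comparison with shared numbers, leaving out pairs of unusual libraries, and counting detected transcripts after rescaling and testing them within pairs, were added after seeing the data. The fit was tested on simulated data with 200 changed transcripts per comparison, with means of at least 5 TPM. Of transcripts changed by 1 on the log2 scale, between 47% (Spirodela NodeTract against Apical) and 68% (Lemna NodeTract against Apical) were recovered in the duckweeds and Pistia. In taro this was 2% for Basal against Apical, 12% for Petiole against Apical and 13% for Sheath against Petiole. Of those changed by 2, at least 84% were recovered in the duckweeds and Pistia, and 55% to 70% in taro. There were between 4 and 14 false calls per simulated comparison, out of 62 to 175 calls. The false calls were 14 of 148 for Lemna LowerWall against Basal and 5 of 62 for taro Basal against Apical. They were 4 of 149 for Spirodela Stipe against NodeTract. The false share was thus above the adjusted p set for a call in most simulated comparisons and below it in the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.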

Results

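RNA was sequenced from dissected body regions of 4 species of the arum family. Lemna minor and Spirodela polyrhiza are duckweeds, free-floating plants whose body is reduced to a leaf-like frond. Pistia stratiotes, the water lettuce, floats as a rosette of leaves joined by stolons, and Colocasia esculenta, taro, is a large rooted herb. The 79 libraries comprised 14 of Lemna, 28 of Spirodela, 20 of Pistia and 17 of taro. Lemna fronds were divided into Apical, Basal and NodeTract regions (n = 4 each) and LowerWall (n = 2). Spirodela was represented by Apical, Basal, LowerWall, NodeTract, Node, Tract and Stipe (n = 4 each), the stipe being the stalk between mother and daughter frond. Pistia was divided into Apical, Basal, Petiole, Stem and Stolon (n = 4 each), and taro into Apical (n = 4), Basal (n = 4), Petiole (n = 6) and Sheath (n = 3). Expression was given in TPM, a unit scaled to a common total per library that carries no read depth, so no counting interval or detection floor is given. Library totals lay between 998999 and 999911 TPM. Transcripts are named by the identifiers of the tables, which do not pair them with gene names.

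To see which regions resembled each other, libraries of a species were correlated on the log2(TPM + 1) scale. Apical and Basal libraries lay close together in every species, with a mean Pearson r of 0.941 in Lemna, 0.938 in Spirodela, 0.934 in Pistia and 0.920 in taro. The Lemna NodeTract stood furthest from the leaf-like regions, at a mean r of 0.736 with Apical and 0.752 with Basal. In Spirodela the lowest mean r was between Stipe and Apical, at 0.711, and in Pistia between Stem and Apical, at 0.679. The Pistia Petiole and Stolon were close to each other, with a mean r of 0.921. Taro Sheath and Petiole had a mean r of 0.699, the lowest of the taro regions. Mean correlations within a region ranged from 0.859 for taro Sheath to 0.971 for Lemna Apical. The library closest to a given library came from its own region for 13 of 14 Lemna, 27 of 28 Spirodela, 15 of 20 Pistia and 9 of 17 taro libraries. These correlations are across transcripts, which are not independent replicates.

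**Figure D1:**
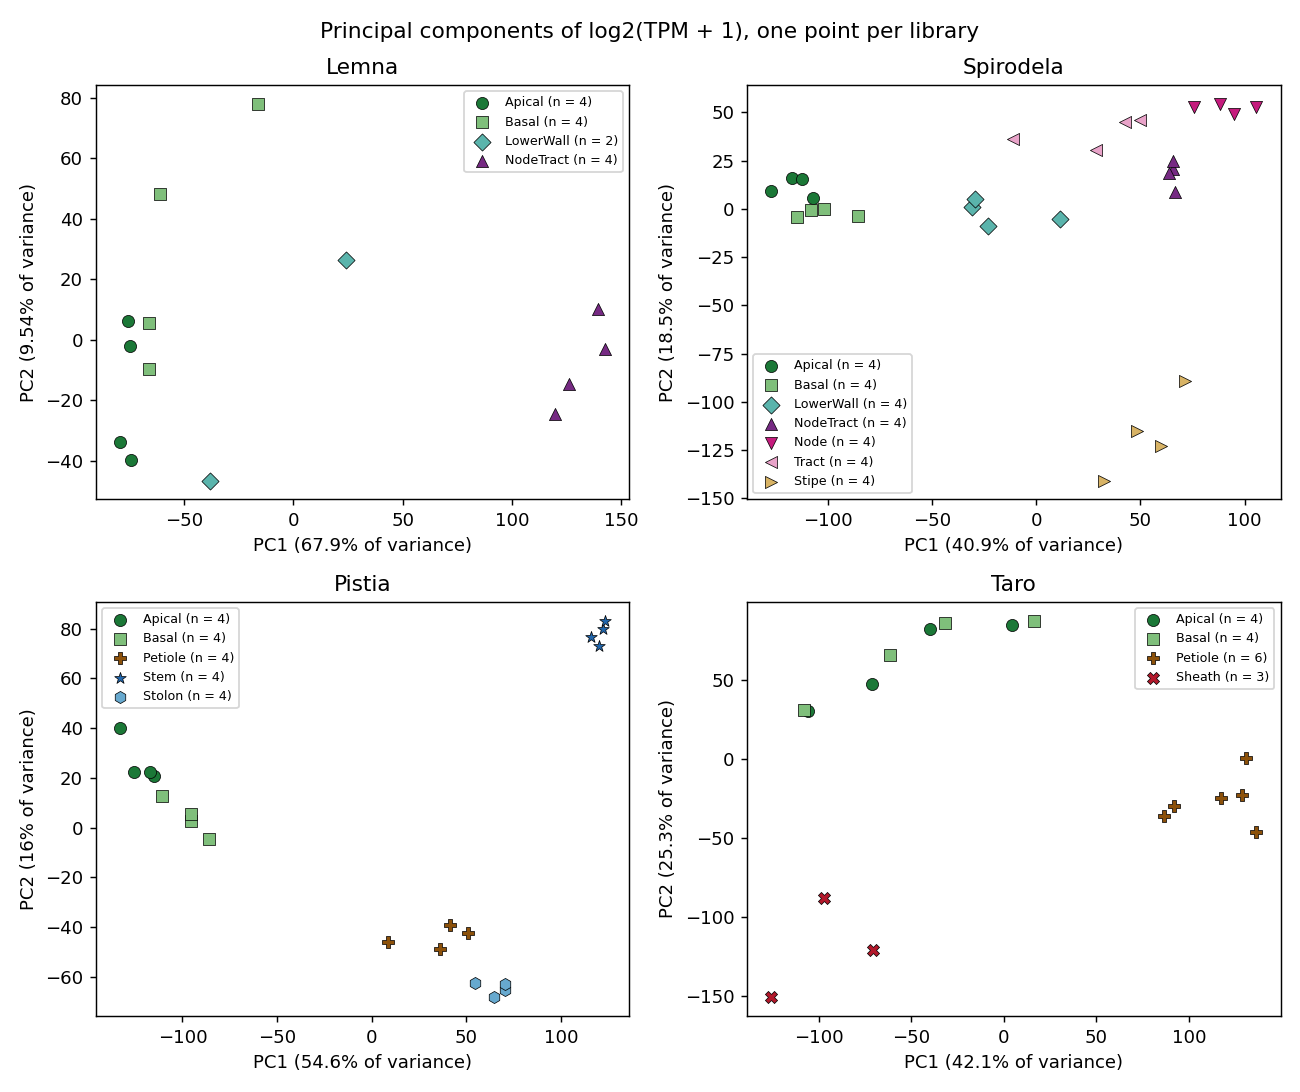
Principal components of log2(TPM + 1) for each species, with each library as a point coloured by region and the share of variance of each component on its axis. On the first component Apical and Basal libraries lie near each other in Lemna, Spirodela and Pistia except Lemna Basal replicate 3, which lies between the other Basal libraries and NodeTract. In taro the Apical and Basal libraries of the same number lie together and those of different numbers are spread along that component. Lemna NodeTract, Pistia Stem and taro Petiole lie apart on it, while Spirodela Stipe and taro Sheath lie apart only on the second component. The first component holds 67.9% of the variance in Lemna, 40.9% in Spirodela, 54.6% in Pistia and 42.1% in taro.

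The number of transcripts at 1 TPM or more differed between regions. Lemna NodeTract had 14139 ± 129 transcripts (SD, n = 4), against 12150 ± 143 in Apical (n = 4) and 12588 ± 429 in Basal (n = 4). Spirodela NodeTract had 14808.5 ± 99.2 and Apical 12750.5 ± 131 (n = 4 each). In Pistia the count was 14717 ± 283 in Apical, 16384 ± 194 in Petiole and 17364 ± 86.9 in Stem (n = 4 each). These differences were among 14 of the 19 comparisons with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries can give, and with an adjusted p of 0.0362 over the 19. These permutations ignored the replicate numbers. Lemna NodeTract against Apical and Pistia Stem against Apical were among those whose numbers pair the libraries, and there an exact permutation test within pairs gave p = 0.125, the smallest that 4 pairs can give, so that test is too small to decide. Taro Sheath had fewer transcripts than Petiole, at 13448 ± 1286 (n = 3) against 16486 ± 538 (n = 6), with an exact permutation p of 0.0119 and an adjusted p of 0.0362. The minimum of 1 TPM was stricter in Sheath, where median-of-ratios size factors were 0.355 to 0.774 against 1.06 to 1.43 in Petiole. After rescaling, a check chosen after these counts were seen, the means were 14430 ± 586 and 16193 ± 402, so the size of the difference depends on the scale, with the exact permutation p again 0.0119. Rescaling also lowered the excess of Lemna NodeTract over Apical from 1989 to 1772 transcripts, of Spirodela NodeTract over Apical from 2058 to 1788 and of Pistia Stem over Apical from 2646.5 to 2227, with the permutation p again 0.0286 for each. The 4 other comparisons did not pass: the exact permutation p was 0.600 for Lemna LowerWall against Basal (n = 2 and 4, where 0.0667 is the smallest possible), 0.0571 for Spirodela Basal against Apical (n = 4 each), 0.971 for taro Basal against Apical (n = 4 each) and 0.248 for taro Petiole against Apical (n = 6 and 4).

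**Figure D2:**
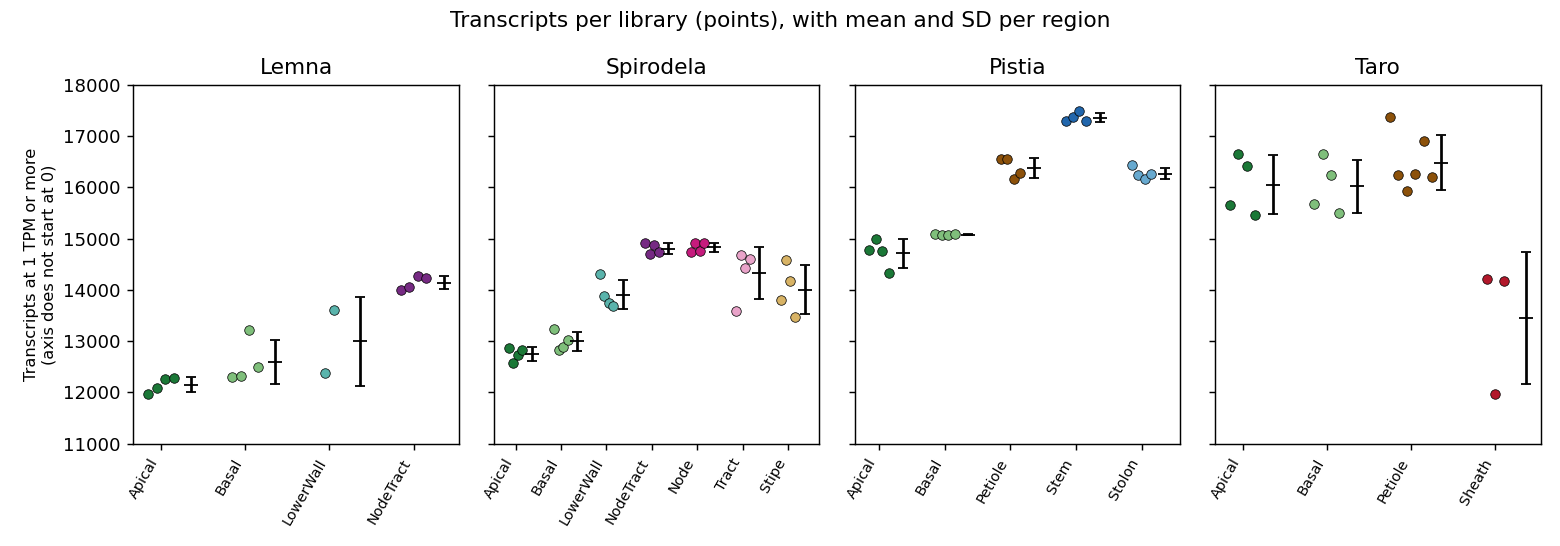
Transcripts at 1 TPM or more in each library (points) by region, with the mean and SD of each region beside them. The vertical axis does not start at 0. Pistia Stem, at a mean of 17364, has the highest mean of the 20 groups, and the 3 taro Sheath libraries lie below every other taro library.

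To find expression that distinguished the parts of the Lemna frond, regions were compared within a fit over all 14 libraries. Basal and Apical differed in 383 of 14687 transcripts, 281 higher and 102 lower in Basal. Lm7210a016g001040_T001 averaged 184 ± 209 TPM in Basal (SD, n = 4) and 0.0911 ± 0.182 in Apical (n = 4), and Lm7210a003g004680_T001 averaged 541 ± 725 and 1.75 ± 1.97. Both were thus higher in Basal with a spread between Basal libraries as large as the mean, at log2 differences of 6.68 (SE 1.00, limma adjusted p = 0.0044) and 6.64 (SE 1.18, adjusted p = 0.0118). Lm7210a013g000780_T001 was lower, at 0.435 ± 0.165 in Basal against 60.8 ± 12.9 TPM in Apical (limma adjusted p = 1.9e-08), and so was Lm7210a003g001190_T001, at 0.318 ± 0.376 against 45.1 ± 35.4 (adjusted p = 0.0026). Libraries with the same number deviated together in this pair of regions, and with the replicate number as a block 1141 transcripts were called, 812 higher and 329 lower in Basal. With only the Basal and Apical libraries in the fit 310 were called, 160 higher and 150 lower. With the block in that smaller fit 1335 were called, 732 higher and 603 lower, so the excess of higher calls depended on the fit. Leaving out any 1 Apical library, or Basal replicate 1, 3 or 4, lowered the count, to between 142 without Apical replicate 1 and 234 without Basal replicate 1.

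NodeTract differed from both leaf-like regions of Lemna in about as many transcripts. Against Apical 9943 were called, 67.7% of those tested, with 7706 higher and 2237 lower in NodeTract. Lm7210a002g004250_T001 averaged 2077 ± 713 TPM in NodeTract and 0.939 ± 1.13 in Apical (SD, n = 4 each), a log2 difference of 10.21 (SE 1.09, limma adjusted p = 2.8e-06). Lm7210a001g010140_T001 averaged 1420 ± 381 and 1.00 ± 0.501 TPM, a log2 difference of 9.47 (limma adjusted p = 1.0e-06). Lower in NodeTract were Lm7210a020g005440_T001, at 4.43 ± 7.56 against 343 ± 288 TPM, and Lm7210a003g000860_T001, at 1.81 ± 0.849 against 177 ± 169. Against Basal 9730 were called, 7425 higher and 2305 lower. The same Lm7210a003g000860_T001 stood at 323 ± 168 TPM in Basal, and Lm7210a002g006240_T001 at 2634 ± 1552 in Basal against 27.3 ± 22.2 in NodeTract. Lm7210a001g002350_T001 averaged 1146 ± 499.9 TPM in NodeTract and 17.4 ± 28.1 in Basal, and Lm7210a021g004530_T001 391 ± 341 and 5.43 ± 9.66. The excess of higher calls depended on the scale: after median-of-ratios rescaling the split was 5524 higher and 4261 lower against Apical, and 5311 and 4194 against Basal. The median log2 difference over all transcripts moved from 0.61 to 0.11 and from 0.56 to 0.09 with that rescaling.

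LowerWall differed from Basal in 974 Lemna transcripts, 515 higher and 459 lower in LowerWall. Lm7210a003g000880_T001 averaged 2519 ± 265 TPM in LowerWall (SD, n = 2) and 11.9 ± 9.85 in Basal (n = 4), a log2 difference of 7.90 (SE 0.58, limma adjusted p = 8.0e-06). Lm7210a008g009460_T001 averaged 1185 ± 63.0 and 12.1 ± 8.06 TPM, a log2 difference of 6.70 (limma adjusted p = 4.6e-06). Lm7210a006g007060_T001 was lower, at 1.05 ± 0.334 against 68.7 ± 23.1 TPM, and Lm7210a016g000660_T001 lower at 3.61 ± 5.11 against 179 ± 110.1. The call of Lm7210a016g000660_T001 was lost with only these regions in the fit (limma adjusted p = 0.0672) and without LowerWall replicate 2 (log2 difference -4.21, adjusted p = 0.0840). Rescaling turned the majority, with 337 higher and 730 lower, and moved the median log2 difference from 0.20 to 0.05. With only the libraries of these regions in the fit 233 transcripts were called, and limma called 0 with the replicate number as a block in that fit, with 3391 at an unadjusted p under 0.05. The count was 386 without LowerWall replicate 4, 581 without Basal replicate 1, 530 without Basal replicate 4 and 2060 without NodeTract replicate 1.

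The Spirodela frond was compared in the same way, with all 28 libraries in the fit. Basal and Apical differed in 234 of 15802 transcripts, 128 higher and 106 lower in Basal, and after rescaling 127 and 176. Sp9509d001g004260_T001 averaged 64.0 ± 53.1 TPM in Basal and 1.75 ± 1.79 in Apical (SD, n = 4 each), a log2 difference of 4.22 (SE 0.71, limma adjusted p = 0.0019). Sp9509d002g012120_T001 averaged 42.7 ± 36.4 and 1.49 ± 2.34 TPM, a log2 difference of 3.98 (limma adjusted p = 0.0060). Sp9509d017g002110_T001 fell from 562 ± 599 TPM in Apical to 4.07 ± 0.571 in Basal, and Sp9509d017g002190_T001 from 669 ± 435 to 9.03 ± 10.2 (limma adjusted p = 8.4e-05 and 0.00024). The replicate number paired these libraries, and with it as a block the count was 435. That fit left out the Node libraries, which have no number, and put Tract libraries in the blocks of the same numbers. The change is thus not that of the block alone. In a fit of the Basal and Apical libraries alone 37 transcripts were called, with Sp9509d017g002110_T001 the only one of the 4 named here among them, and with the block in that smaller fit limma called 0, with 3471 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0791. The count was 113 without Apical replicate 2, 103 without Apical replicate 3, 99 without Basal replicate 3, 153 without Basal replicate 4 and 363 without Tract replicate 1.

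NodeTract of Spirodela differed from Apical in 8656 transcripts, 6671 higher and 1985 lower, and from Basal in 8253, 6027 higher and 2226 lower. Sp9509d002g012120_T001, already higher in Basal than Apical, reached 827 ± 178 TPM in NodeTract (SD, n = 4), a log2 difference of 8.77 from Apical (SE 0.76, limma adjusted p = 1.7e-09). Sp9509d010g001420_T001 averaged 575 ± 178 TPM in NodeTract against 0.470 ± 0.940 in Apical (limma adjusted p = 3.2e-06). Sp9509d010g009070_T001 was lower, at 11.6 ± 9.58 TPM in NodeTract against 6053 ± 1728 in Apical and 7415 ± 2374 in Basal, with log2 differences of -9.26 and -9.54. Sp9509d010g006020_T001 showed the same direction, at 17.0 ± 20.1 TPM against 5028 ± 2288 in Apical and 11686 ± 10311 in Basal. Sp9509d018g002570_T001 averaged 439.8 ± 243 TPM in NodeTract and was listed at 0 in all 4 Basal libraries. Sp9509d005g002620_T001 averaged 232 ± 60.1 TPM in NodeTract and 3.06 ± 6.12 in Basal (limma adjusted p = 6.6e-07). After rescaling the splits were 4732 higher and 3415 lower against Apical, and 4731 and 3363 against Basal. The median log2 difference moved from 0.47 to 0.11 against Apical and from 0.38 to 0.13 against Basal.

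LowerWall of Spirodela differed from Basal in 4502 transcripts, 2837 higher and 1665 lower, or 2459 and 2196 after rescaling, which moved the median log2 difference from 0.19 to 0.09. Sp9509d017g002190_T001, which was lower in Basal than Apical, averaged 4459.5 ± 3571 TPM in LowerWall (SD, n = 4) against 9.03 ± 10.2 in Basal, a log2 difference of 8.76 (SE 0.87, limma adjusted p = 4.5e-08). Sp9509d017g002170_T001 averaged 1309 ± 2249 TPM in LowerWall and 1.93 ± 3.86 in Basal (limma adjusted p = 0.00018), the mean being carried by a single library. Lower in LowerWall were Sp9509d010g006020_T001, at 8.33 ± 6.79 against 11686 ± 10311 TPM, and Sp9509d010g006000_T001, at 2.39 ± 2.54 against 2195 ± 2131, with log2 differences of -10.10 and -9.23.

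The stipe was set against the frond blade and against NodeTract. Stipe differed from Apical in 8803 transcripts, 6199 higher and 2604 lower, or 4663 and 3576 after rescaling, with the median log2 difference moving from 0.41 to 0.13. Sp9509d011g001260_T001 averaged 9480.3 ± 2289 TPM in Stipe and 3.44 ± 3.74 in Apical (SD, n = 4 each), a log2 difference of 11.35 (SE 0.54, limma adjusted p = 4.0e-14). Sp9509d001g011480_T001 averaged 2981 ± 1455 TPM in Stipe and was listed at 0 in the 4 Apical libraries. Sp9509d002g012090_T001, which averaged 39531 ± 11870.4 TPM in Apical, fell to 72.0 ± 69.6 in Stipe, and Sp9509d012g001160_T001 fell from 2655 ± 1902 to 1.26 ± 1.94 (limma adjusted p = 3.5e-09 and 1.7e-09). Against NodeTract 7226 transcripts were called, 3059 higher and 4167 lower in Stipe. Sp9509d002g012110_T001 averaged 9747 ± 1695 TPM in Stipe and 76.4 ± 91.8 in NodeTract, and Sp9509d001g011470_T001 482 ± 406 and 0.597 ± 1.19. Sp9509d018g002570_T001 was listed at 0 in all 4 Stipe libraries, and Sp9509d012g001160_T001 averaged 576 ± 529 TPM in NodeTract.

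Node and Tract, which carry a separate block of labels with a protocol text of their own, were set against each other. Node differed from Tract in 3936 transcripts, 3124 higher and 812 lower, or 1719 and 1368 after rescaling, which moved the median log2 difference from 0.28 to 0.06. Sp9509d018g002570_T001 averaged 649 ± 483 TPM in Node (SD, n = 4) and was listed at 0 in the 4 Tract libraries. Sp9509d005g003790_T001 averaged 89.2 ± 31.5 TPM in Node and 0.659 ± 1.32 in Tract, a log2 difference of 5.97 (SE 0.51, limma adjusted p = 1.4e-08). Sp9509d019g000970_T001 was lower in Node, at 5.59 ± 11.2 against 102 ± 56.1 TPM (limma adjusted p = 0.0010), and Sp9509d017g004740_T001 averaged 27.4 ± 15.6 TPM in Tract and was listed at 0 in the 4 Node libraries. Tract replicate 1 stood apart in the share of its 10 most abundant transcripts, and without it 1861 transcripts were called. The count was 1999 without the Node column numbered 3, and 1899 with only Node and Tract libraries in the fit.

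Pistia, with a conventional leaf and stem, gives the same questions on a larger rosette. Basal and Apical leaf differed in 230 of 18727 transcripts, 223 higher and 7 lower in Basal. Pis17636.t1 averaged 296 ± 227 TPM in Basal and 11.1 ± 11.2 in Apical (SD, n = 4 each), a log2 difference of 4.94 (SE 0.65, limma adjusted p = 0.00053), and Pis16854.t1 57.6 ± 31.5 and 2.87 ± 2.63 (log2 difference 4.04, adjusted p = 0.00043). Lower in Basal were Pis14241.t1, which fell from 19.5 ± 3.31 to 8.12 ± 1.77 TPM, and Pis07475.t1, from 147 ± 30.6 to 73.5 ± 16.2 (limma adjusted p = 0.0259 and 0.0227). With only the Basal and Apical libraries in the fit 1 transcript was called, Pis07060.t2, which was listed at 0 in Basal and averaged 0.621 TPM in Apical and was singled out after its values were seen. The call of Pis14241.t1 was lost without Apical replicate 1 (limma adjusted p = 0.0512) or 4 (0.0836) and without Basal replicate 1 (0.0581) or 4 (0.108). The call of Pis07475.t1 was lost without Apical replicate 1 (limma adjusted p = 0.0549) or 4 (0.0770) and without Basal replicate 2 (0.0814) or 4 (0.0623), and with a pseudocount of 0.1 (0.0794). The count was 134 without Basal replicate 1, 152 without Basal replicate 4 and 367 without Basal replicate 3, and 4 of the 35 divisions of these libraries into groups of 4, the real one included, gave as many calls.

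Petiole differed from Apical leaf of Pistia in 9065 transcripts, 6675 higher and 2390 lower, or 5213 and 3844 after rescaling, with the median log2 difference moving from 0.32 to 0.11. Pis03779.t1 averaged 653 ± 169 TPM in Petiole and 0.654 ± 1.31 in Apical (SD, n = 4 each), a log2 difference of 8.85 (SE 0.52, limma adjusted p = 1.8e-10), and Pis03257.t1 624 ± 382 and 0.764 ± 1.53. Pis14142.t1 fell from 9423 ± 3827 TPM in Apical to 72.6 ± 15 in Petiole, and Pis18958.t1 from 246 ± 97.0 to 1.59 ± 0.722. Stem differed from Apical in 11949 transcripts, 63.8% of those tested, with 9052 higher and 2897 lower, or 6807 and 4713 after rescaling, with a median of 0.54 and then 0.15. Pis10384.t1 averaged 870.2 ± 108 TPM in Stem and was listed at 0 in the 4 Apical libraries, and Pis15816.t1 averaged 906 ± 189 TPM against 0.151 ± 0.10. Pis14142.t1 stood at 16.2 ± 11.9 TPM in Stem, a log2 difference of -9.19 from Apical, and Pis08910.t1 at 0.799 ± 0.848 against 378 ± 51.8.

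Stem also differed from Petiole in 8295 Pistia transcripts, 5725 higher and 2570 lower, or 4660 and 3495 after rescaling, with a median of 0.21 and then 0.04. Pis15816.t1 and Pis10384.t1 were again higher in Stem, with 6.23 ± 8.02 and 7.05 ± 7.92 TPM in Petiole (log2 differences 7.47 and 7.43, limma adjusted p = 1.4e-09 and 4.8e-09). Pis03779.t1 and Pis03777.t1 were lower, at 9.04 ± 6.93 and 6.75 ± 4.86 TPM in Stem against 653 ± 169 and 412 ± 98.4 in Petiole. Stolon differed from Stem in 7949 transcripts, 2573 higher and 5376 lower, or 3738 and 4264 after rescaling, with a median of -0.18 that rescaling brought to -0.0014. Pis19154.t1 averaged 431 ± 122 TPM in Stolon and 5.02 ± 5.85 in Stem, and Pis04049.t1 269 ± 73.5 and 2.94 ± 2.13 (limma adjusted p = 6.2e-07 and 1.9e-10). Pis10384.t1 fell to 0.190 ± 0.381 TPM in Stolon, and Pis18898.t1 from 577 ± 56.5 in Stem to 0.390 ± 0.415.

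Taro Basal and Apical leaf were compared to ask whether the blade of a large leaf is divided in the same way. Of 18717 transcripts limma called 0, with 36 at an unadjusted p under 0.05. Without Basal replicate 3 it called 1, EVM0020565.1, which averaged 2.82 TPM in Basal and was listed at 0 in Apical, and which was singled out after its values were seen. Libraries of the same number were close: Basal replicate 4 and Apical replicate 4 had the largest shares of TPM in EVM0020882.1 among the leaf libraries, at 12% and 14.9%. A fit of these libraries alone with the replicate number as a block also called 0, with 1111 at an unadjusted p under 0.05 and a smallest adjusted p of 0.733. In simulated data with these group sizes and no pairing, the fit without a block recovered 2% of transcripts changed by 1 on the log2 scale and 55% of those changed by 2.

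Petiole differed from Apical leaf of taro in 6965 transcripts, 4474 higher and 2491 lower, or 3571 and 3334 after rescaling, which moved the median log2 difference from 0.25 to 0.02. EVM0026502.1 averaged 4177 ± 2228 TPM in Petiole (SD, n = 6) and 8.33 ± 15.5 in Apical (n = 4), a log2 difference of 10.22 (limma adjusted p = 3.0e-06). EVM0007570.1 averaged 5264 ± 2399.8 and 18.2 ± 33.9 TPM, a log2 difference of 9.99 (limma adjusted p = 9.3e-06). EVM0003519.1 was lower, at 0.438 ± 0.470 in Petiole against 192 ± 135 TPM, and EVM0010199.1 averaged 124 ± 93.1 TPM in Apical and was listed at 0 in all 6 Petiole libraries. Petiole RNA came from pooled aliquots with a further cleanup and leaf RNA did not, so extraction and region cannot be told apart here.

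Sheath, the base of the taro leaf that clasps the stem, was dominated by few transcripts. EVM0020882.1 made up 30.1% ± 1.46 of the TPM of Sheath (SD, n = 3) and EVM0021315.1 averaged 13.5%, against 0.672% and 0.790% in Petiole (n = 6). The 10 most abundant transcripts of each library held 55.5% ± 7.12 of TPM in Sheath and 11.6% ± 2.36 in Petiole (exact permutation p = 0.0119, the smallest these group sizes can give, adjusted p = 0.0905 over the 19 comparisons). Sheath differed from Petiole in 10836 transcripts, 880 higher and 9956 lower, with a median log2 difference of -1.02. After rescaling 6561 were called, 2662 higher and 3899 lower, with a median of -0.17. EVM0025519.1 averaged 1009 ± 305 TPM in Sheath and 5.77 ± 7.73 in Petiole (limma adjusted p = 0.0036), and EVM0020882.1 rose by 6.80 on the log2 scale (SE 1.63, limma adjusted p = 0.0024). EVM0015590.1 and EVM0000784.1 averaged 6121 ± 2076 and 1424 ± 1095 TPM in Petiole and were listed at 0 in all 3 Sheath libraries.

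**Figure D3:**
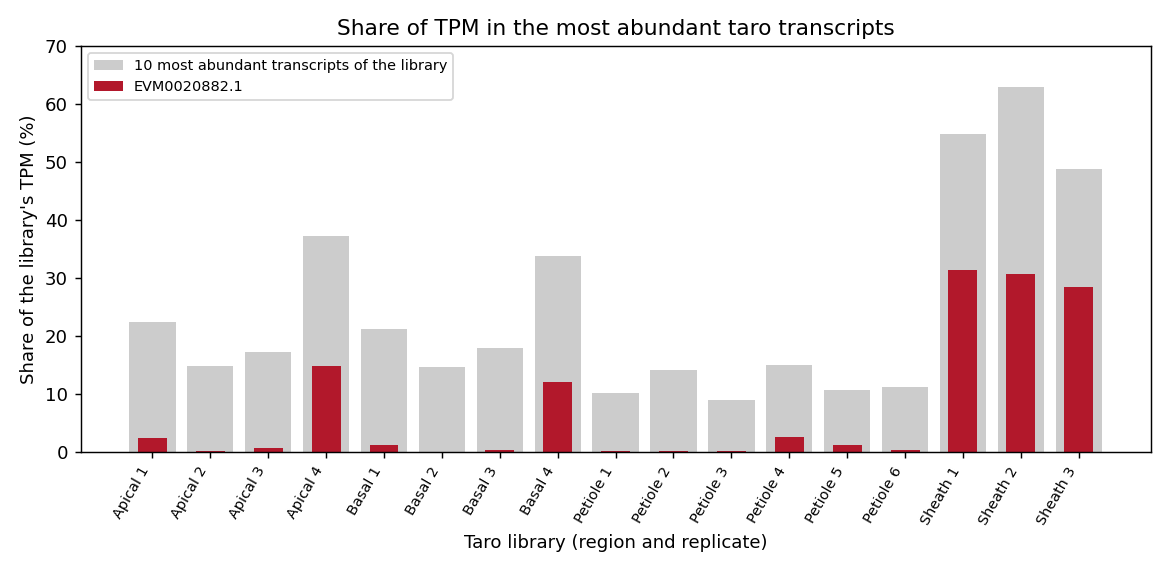
Share of each taro library's TPM held by its 10 most abundant transcripts (wide grey bars) and by EVM0020882.1 (narrow red bars). EVM0020882.1 holds between 28.5% and 31.3% in the 3 Sheath libraries, 14.9% in Apical 4 and 12% in Basal 4.

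Transcripts higher in a single region than in each other region of the species were then counted. Such a count cannot exceed the higher calls against the most similar region sampled, and transcripts low in a region are not counted. In Pistia, for instance, 7 transcripts were higher in Apical than Basal, so no more could be specific to Apical. The counts are therefore no measure of distinctness by themselves. In Lemna 5217 transcripts were specific to NodeTract, 104 to LowerWall, 65 to Basal and 22 to Apical, a sum of 5408 that was 3511 without LowerWall replicate 2. In Spirodela, with Node and Tract left out of the regions compared but kept in the fit, 2049 were specific to Stipe, 1725 to NodeTract, 230 to LowerWall, 23 to Basal and 3 to Apical. In Pistia 3962 were specific to Stem, 352 to Stolon, 192 to Petiole, 5 to Apical and 2 to Basal. In taro 3508 were specific to Petiole and 293 to Sheath, and limma gave 0 for Apical and Basal, between which it made no calls. Petiole and Sheath RNA was extracted unlike leaf RNA, so extraction and region cannot be told apart in the taro counts. Rescaling lowered the sum over regions from 5408 to 4048 in Lemna and from 4030 to 3568 in Spirodela. In Pistia the sum fell from 4513 to 3465 and in taro from 3801 to 2796. The counts of single regions were not made after rescaling. The 3 Apical-specific transcripts of Spirodela, named after their values were seen, were Sp9509d009g005430_T001, Sp9509d012g001160_T001 and Sp9509d017g004780_T001, with Apical means of 10.5, 2655 and 20.1 TPM. Among the Node and Tract libraries, which that count leaves out, Sp9509d012g001160_T001 averaged 2422 ± 1661 and 4758 ± 2239 TPM (SD, n = 4 each), so it was not specific to Apical among all 7 regions. Chosen in the same way, the Basal-specific Pis06196.t1 and Pis11683.t1 of Pistia averaged 6.42 and 8.60 TPM, and the Apical-specific Pis00389.t1, Pis00885.t1, Pis01143.t1, Pis07475.t1 and Pis18799.t1 averaged 3.17, 8.09, 3.94, 147 and 3.05 TPM. With only the Basal and Apical libraries in the fit, none of these named transcripts of either species was called between Basal and Apical, with a smallest limma adjusted p of 0.0616 in Spirodela and 0.135 in Pistia, so these lists rest on the fit over all regions. No test compared species, because the tables do not pair their transcripts.

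**Figure D4:**
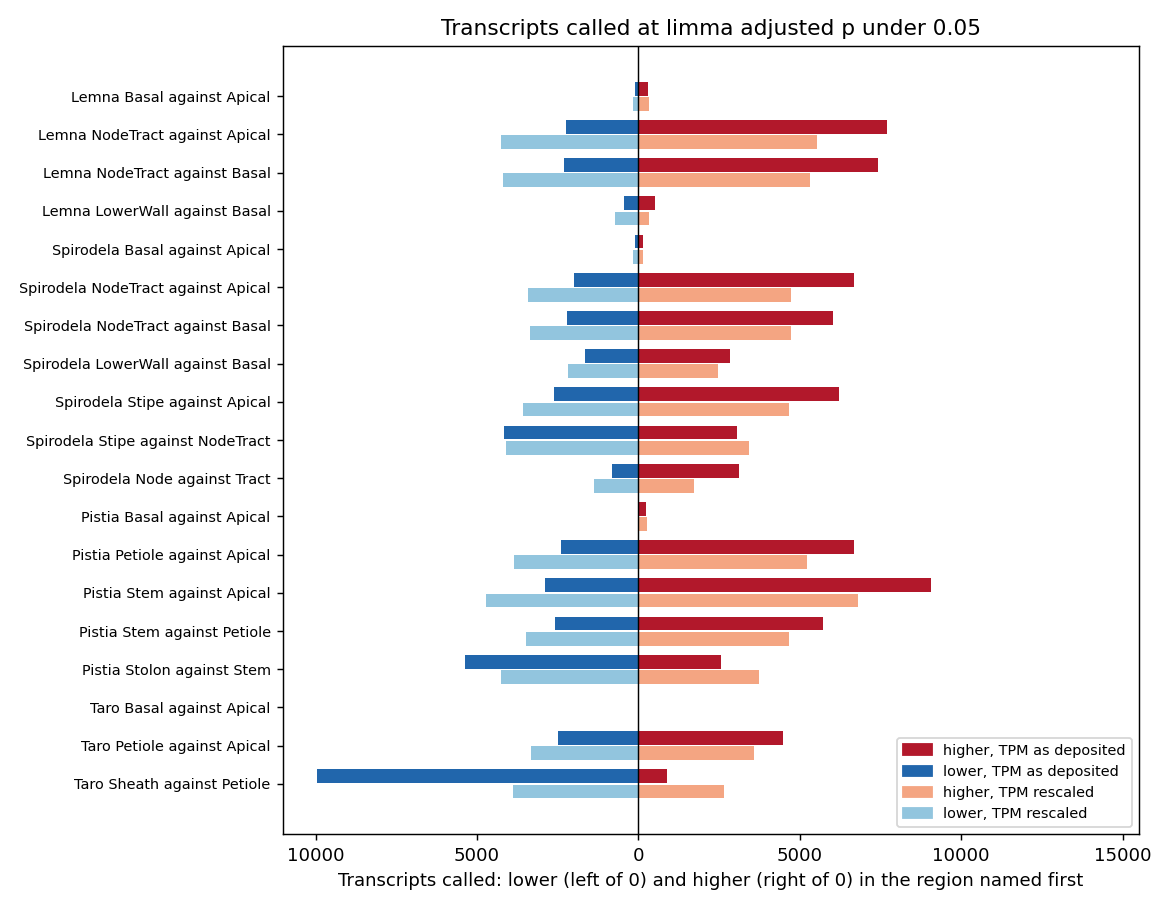
Transcripts called higher (right of 0) or lower (left of 0) in the region named first, for each of the 19 comparisons, with TPM as deposited (dark bars) and after median-of-ratios rescaling (light bars). Basal against Apical gave the lowest count of each species, from 0 in taro to 383 in Lemna. The largest change of split with rescaling was in taro Sheath against Petiole, from 880 higher and 9956 lower to 2662 and 3899.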

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

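Of the tests in this part, those of the taro excess of lower calls and of the common factor behind it were chosen only after the result was seen, as was the count by the mean over all libraries. The other tests were written down before their result was seen, for patterns that had been noticed in the same data.

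In 9 of 129 tests, each of 1 measure or named transcript in 1 group of libraries, a single library stood apart from the rest of its group, by the gap to its nearest neighbour as a fraction of the range of the group. For independent, normally distributed values this fraction, Dixon's ratio, would be flagged in about 1 in 20 tests, or 6.45 here. Named transcripts were tested on the TPM scale and measures of a library are related, so the rate expected here is not known. Lemna Basal replicate 3 had 59.6 TPM of Lm7210a001g002350_T001, against 2.93 to 3.78 in the other Basal libraries (fraction 0.985). Lemna NodeTract replicate 1 had 3140.1 TPM of Lm7210a002g004250_T001, against 1662 to 1825 (fraction 0.890). Pistia Apical replicate 4 had an effective number of transcripts, a measure of evenness, of 2721 against 1892 to 1993 (fraction 0.879), and 11.9% of TPM in its 10 most abundant transcripts against 16.2% to 16.9% (fraction 0.858). Pistia Stem replicate 1 had 34.0 TPM of Pis14142.t1 against 9.60 to 11 (fraction 0.942). Spirodela LowerWall replicate 1 had 4680.2 TPM of Sp9509d017g002170_T001 against 119.9 to 305 (fraction 0.959). Spirodela Stipe replicate 4 had an effective number of 2133 against 3183 to 3357 (fraction 0.858). Spirodela Tract replicate 1 held 27.0% of TPM in its 10 most abundant transcripts against 15.9% to 16.5% (fraction 0.944). Taro Apical replicate 2 had 69.1 TPM of EVM0007570.1 against 0 to 3.16 (fraction 0.954).

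Lemna Basal replicate 3 and LowerWall replicate 4 lay towards NodeTract, and the design gives no biological explanation to test beyond a state shared by libraries of the same number. No like gain was seen in Apical: NodeTract-specific transcripts gained a median of 0% of their NodeTract level in Apical replicate 3 and 0.0293% in Apical replicate 4, against 4.21% in Basal replicate 3 and 16.1% in LowerWall replicate 4. But the Apical libraries took part in choosing these transcripts as lower in Apical, while Basal replicate 3 and LowerWall replicate 4 did not. The shares are thus not measured alike, and a state shared by number stays open. For LowerWall replicate 4, NodeTract tissue carried into the piece is a candidate explanation: 87.0% of these transcripts rose, 9 of the 10 most abundant among them, and the gain was 0.870 times as large in the more as in the less abundant ones. The baseline was a single library, however, which also helped choose these transcripts as low in LowerWall, and that favours a rise. For Basal replicate 3 carry-over and other causes cannot be told apart: the ratio was 0.676, but 67.9% rose, between the bounds set for either outcome, and 5 of the 10 most abundant did. Without both libraries 374 transcripts were called between LowerWall and Basal instead of 974.

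Taro Sheath had 9956 transcripts lower and 880 higher than Petiole, with EVM0020882.1 at 30.1% of its TPM. Whether a few transcripts with a large share of the total account for the excess of lower calls stays open: 40.6% of the calls were higher in Sheath after rescaling, but rescaling centres the ratios whatever the cause. A common factor is argued against as the whole cause of the lower transcripts: 17.7% of those tested, 3315 transcripts, were still lower by at least 1 on the log2 scale after rescaling. Loss of transcripts because fewer reads remain for the rest stays open as a part of it. Of 2997 transcripts with a Petiole mean of at least 50 TPM 616, 20.6%, were still lower, but choosing by a high Petiole mean favours transcripts lower in Sheath. By lists chosen only after that result was seen, the share was 14.6% by the mean over all libraries (383 of 2615), 9.67% by the mean over Apical and Basal (241 of 2491) and 3.73% by the Sheath mean (61 of 1635), a choice that favours the reverse. Both regions had the same extraction per the labels, and a difference between the tissues stays open, as untested.

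In Spirodela the NodeTract mean lay outside the range of the Node and Tract means by more than 0.5 on the log2 scale for 22.4% of the tested transcripts. Among the 4356 called between NodeTract and the mean of Node and Tract it did so for 2721, 839 above and 1882 below. That share of 62.5%, or 58.6% after rescaling and 59.4% to 71.4% when single libraries were left out, says nothing for or against a difference between the label blocks, because these transcripts were chosen for differing from that mean. The blocks differ in dissection as well as in protocol text, so handling and tissue cannot be told apart.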

How the results depend on the processing

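The block in fits of the compared regions alone, and leaving out pairs of libraries, were tests chosen only after the result was seen; the rest were planned. Counts more than 1.5 times above or below those reported arose mainly in Basal against Apical, and the cause was not tested except where stated. With the replicate number as a block the count was 1141 for Lemna Basal against Apical and 1712 for Lemna LowerWall against Basal. It was 435 for Spirodela Basal against Apical, in a fit without the unnumbered Node libraries, and 402 for Pistia Basal against Apical. The block moved no other count that far. With the compared regions alone, a fit with fewer libraries, it was 233 for Lemna LowerWall against Basal, 37 for Spirodela and 1 for Pistia Basal against Apical, and 1899 for Spirodela Node against Tract, the same 1899 as with the label blocks fitted separately. With the block in that smaller fit it was 1335 for Lemna Basal against Apical, and limma called 0 for Spirodela Basal against Apical, with 3471 at an unadjusted p under 0.05, 0 for Lemna LowerWall against Basal, with 3391, and 0 for Pistia Basal against Apical, with 1533; it was 4064 for taro Sheath against Petiole. A pseudocount of 0.1 gave 410 for Spirodela and 376 for Pistia Basal against Apical. Rescaling gave 6561 for taro Sheath against Petiole, and leaving out Basal 3 and LowerWall 4 gave 374 for Lemna LowerWall against Basal. No filter and Spearman correlation moved no result that far. No paired analysis was possible for Spirodela Node against Tract because the Node columns are numbered 1, 3, 5 and 6, unlike their labels, and the gene-list alternatives were not run.

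Leaving out single libraries gave 142 to 563 calls for Lemna Basal against Apical, 386 to 2060 for Lemna LowerWall against Basal, 3511 to 6614 for Lemna region-specific transcripts, 99 to 363 for Spirodela Basal against Apical, 1861 to 4952 for Node against Tract, 134 to 367 for Pistia Basal against Apical and 0 to 1 for taro Basal against Apical. For Lemna Basal against Apical the libraries that moved it were Apical 1 (142), Apical 2 (200), Apical 3 (199), Apical 4 (172), Basal 1 (234), Basal 3 (222) and Basal 4 (170). For LowerWall against Basal they were LowerWall 4 (386), Basal 1 (581), Basal 4 (530) and NodeTract 1 (2060), and for the region-specific sum LowerWall 2 (3511). A LowerWall library left alone was assumed to vary like the other groups. For Spirodela Basal against Apical they were Apical 2 (113), Apical 3 (103), Basal 3 (99), Basal 4 (153) and Tract 1 (363), and for Node against Tract the Tract 1 (1861) and Node column 3 (1999) libraries. For Pistia they were Basal 1 (134), Basal 4 (152) and Basal 3 (367), and for taro Basal 3 (1). Of 1048 values of named transcripts under alternatives, 1018 kept direction and call, 30 kept direction and lost the call, and 0 reversed. These transcripts were chosen for large called differences without overlap, which favours keeping the call, and 571 of those kept were leave-one-out values. All 30 losses fell in Lemna LowerWall against Basal and in Basal against Apical of Spirodela and Pistia. With the block in fits of the compared regions alone, every named transcript of these comparisons lost its call, 12 values.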

Other observations

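The divisions of libraries into other groups, and the region pairs and transcript families singled out here, were tests chosen only after the result was seen. Setting Basal against Apical lists, and leaving out the largest region class, were chosen then too. The other tests of Basal transcripts and of neighbouring identifiers were written down before their result was seen.

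In Lemna 1 of 35 divisions of the libraries, the real one, gave as many calls for NodeTract against Basal (9730, highest other 3). All 4 NodeTract libraries deviated most like the Basal library of their own number, and both regions pair with Apical by number. Chance can thus be excluded there only if these libraries are unpaired. The real division was also 1 of 35 for Basal against Apical (383, highest other 42) and NodeTract against Apical (9943, highest other 1). In both the replicate numbers pair the libraries. For LowerWall, with 2 libraries, no divisions were counted. In Spirodela it was 1 of 35 for each comparison. If the libraries are unpaired, chance can be excluded for NodeTract against Apical (8656, highest other 1), Stipe against Apical (8803, 1967), Stipe against NodeTract (7226, 2402) and Node against Tract (3936, 1298). NodeTract and Apical each pair with Basal by number, and the Node columns could not be matched by number. The numbers pair the libraries for Basal against Apical (234, highest other 36), NodeTract against Basal (8253, 113) and LowerWall against Basal (4502, 1125). In Pistia the real division was again 1 of 35 for Petiole against Apical (9065, highest other 2926), Stem against Petiole (8295, 3) and Stolon against Stem (7949, 5). In each, all 4 libraries of the region named first deviated most like the library of their own number. Chance can thus be excluded only if these libraries are unpaired. For Stem against Apical (11949, highest other 3160) the numbers pair the libraries. For Pistia Basal against Apical 4 of 35 gave as many as the real 230, the others 359, 377 and 410, so chance cannot be excluded.

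For taro Petiole against Apical 1 of 100 divisions gave as many as 6965 (highest other 1144), and for Sheath against Petiole 1 of 84 gave as many as 10836 (highest other 1625), so chance can be excluded for both. For taro Basal against Apical, where limma called 0 with 36 at an unadjusted p under 0.05, all 35 gave as many. That was fixed in advance, because no count can be under 0. The highest, 1744, set numbers 1 and 4 of both regions against numbers 2 and 3, which points to a structure of the samples by replicate number. With the number as a block in a fit of both regions the real division still gave 0, with 1111 at an unadjusted p under 0.05. Where numbers pair the libraries, only 7 other divisions part every pair, too few for a share under 0.05. In each of the 6 such comparisons with calls they gave fewer than the real one: at most 0 in both of Lemna, 1, 0 and 17 in those of Spirodela in the order above, and 1 in Pistia Stem against Apical. For region-specific transcripts 1 of 100 assignments, the real one, gave as many in each species, with the highest of the others at 3 in Lemna, 7 in Spirodela, 2 in Pistia and 187 in taro.

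Some region pairs outside the comparisons were also counted. Pistia Petiole and Stolon lay close, with 2035 transcripts called, 10.9% of those tested, against 8295 between Petiole and Stem. Spirodela LowerWall and Tract differed in 3882 transcripts, 24.6% of those tested. Node and NodeTract differed in 3937, 24.9%, about as many as the 3936 between Node and Tract. Of the 3937, 3237 were higher in Node, a split that was not counted after rescaling. LowerWall and Tract, and Node and NodeTract, join libraries of separate label blocks. In Pistia, where the table holds several transcripts for some genes, 50 of 1524 genes with a call between Stem and Apical had transcripts called in both directions, and 0 of 32 did between Basal and Apical.

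A hypothesis was that the basal part of the leaf or frond holds more of the transcripts of the adjoining proximal region. It was tested on the 200 transcripts most raised in Basal over 2 Apical libraries, by the share that lay above the median of all transcripts in the proximal region against the other Apical libraries. In Pistia this was 82% or 91%, depending on the Apical libraries used, against 30% or 32% of the transcripts most raised in Apical, so the higher level in Basal may follow that of Petiole. These lists are ranks and not calls: with only Basal and Apical in the fit limma called 1 Pistia transcript, lower in Basal. In Spirodela the share was 56.5% or 57% for NodeTract, against 33% or 30.5%, and no bound set for the test was met. In Lemna it was 35.5% or 49% for NodeTract, under the bound set against the hypothesis, but that bound took an even split as no change, and the Apical list gave 26.5% with either set, so it stays open. In taro it was 24.5% or 45.5% for Petiole, against 62.5% or 44%, but with no calls between Basal and Apical these lists decide nothing. The species were not compared with each other.

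A further hypothesis was that transcripts with neighbouring identifiers share their region. Neighbouring pairs specific to the same region numbered 2009 in Lemna, above the highest of 1000 shuffles at 1950, 611 in Spirodela against 519, and 1069 in Pistia against 777. Neighbours were consecutive tested transcripts, and identifiers between them can be missing. In taro the pairs numbered 656, against a shuffle mean of 661, which argues against an excess among consecutive tested transcripts there. Whether directly neighbouring taro identifiers share a region is not decided by it. Without the largest class the number was 250 in Spirodela against a highest shuffle of 229 and 41 in Pistia against 17, which is consistent with neighbours that share a region. In Lemna it was 4, against a shuffle mean of 1.07 and a highest of 7, too few to tell whether the excess extends beyond NodeTract. Reads shared between tandem copies were not tested, and whether the numbering follows the genome is not given in the sources used here.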
